A study of Arabidopsis thaliana with 24 samples.

How the data were processed

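RNA sequencing was carried out on leaves of Arabidopsis thaliana accession Col-0, the common reference line, and of gtl1-4, a knockout line of the trihelix transcription factor gene GTL1. Per the labels, plants were kept well-watered, at 65 to 100% of the water content of the medium, or under water deficit at 30%. Emerging leaves were taken at 1 day after emergence and expanding leaves at 14 to 15 days. Each of the 8 groups has 3 biological replicates, and each replicate pools 10 plants, which gives 24 libraries. All 24 columns were mapped to a sample by name.

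The authors deposited normalized counts in a table for each leaf age, with 37336 gene identifiers and 12 libraries in each. The submitters' processing notes name bcl2fastq, Trimmomatic, FastQC, Trim Galore, STAR and RSEM without versions, and the build TAIR10, while the normalization method is not given in the sources used here. The values deposited by the authors are a normalized signal, namely gene counts divided by 1 size factor per library. In every library all values below 2000 reads were multiples of 0.01 of a common step, and 96.5 to 97.9% of them were whole multiples of it within a tolerance of 0.002, the pattern of estimated counts. Dividing by that step gave the depth of each library. Because a share of the values are fractional, no count model was used. The tables were scaled separately, and no test was made between leaf ages.

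The recovered depth was 14.7 to 43.5 M counts per library in emerging leaves and 14.9 to 27.1 M in expanding leaves. Counts of nuclear genes were 11.4 to 32.8 M and 4.74 to 10.0 M. Replicates of a group differed by more than sampling noise in each group, so none was treated as a repeat of another.

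Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, using lmFit, contrasts and eBayes with a variance trend. Genes with a mean of at least 10 over the 12 libraries of a table were kept, 18529 in emerging and 16522 in expanding leaves. The 12 libraries of a leaf age were fitted together as 4 groups, so that the groups share an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Values after ± are standard deviations between 3 replicates, and SE is the standard error of the fitted log2 fold change. Every adjusted p-value for a gene is from limma, and p-values measure the spread between pooled samples, not between plants.

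There were 29 gene lists with 353 genes, taken from textbook membership, and each was tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists of a comparison. Lists with fewer than 3 tested members had no test. Camera was repeated with the correlation estimated from the data. Of the identifiers, 37051 matched the reference annotation TAIR10.1, which was used for names, neighbours and the GTL1 locus. The genes named are GTL1, the 5 largest rises and 5 largest falls per comparison among called genes with a mean of at least 20 and groups that do not overlap, up to 4 called members of each list, and a fixed set of anthocyanin, polyamine, stomatal and endocycle genes. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

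The procedure was tested on counts simulated from the means, spreads and depths of the real data, for genes with a mean of at least 10. In these 200 genes were changed, drawn from those with a mean of at least 20. False calls were 1.25 to 6.52% of the calls, the highest for the water response of Col-0 in emerging leaves. For the water response of Col-0 in emerging leaves, 76.1% of genes changed 2-fold and 86.4% of those changed 4-fold were recovered. For the interaction these shares were 37.3 and 77.3% in emerging leaves and 22.4 and 63.6% in expanding leaves. Of genes changed 1.5-fold, 31.3% were recovered for the water response of Col-0 in emerging and 17.9% in expanding leaves. For the interaction these were 4.48 and 1.49%, so changes of that size were mostly missed. The alternatives were pseudocounts of 0.5 and 5, no low-value filter, a mean of at least 50, quantile and median-of-ratios scaling, no variance trend, array weights, fits of only the 2 groups compared, a replicate block and leaving out each replicate. Alternatives chosen after seeing the data were limma-voom weights from the recovered depths, leaving out replicates for the correlations, and leaving out 2 libraries per leaf age. In the last case 2 choices were run: libraries picked by eye, and the library farthest from its group together with the farthest of another group.

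Genes with near-identical copies, overlapping genes and antisense genes are uncertain, because RSEM divides shared reads and strand use is not stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.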

Results

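Messenger RNA of whole leaves was sequenced in a 2 by 2 design of genotype and water supply at 2 leaf ages, with 3 libraries in each of 8 groups. The series title places the question in the repression of GTL1 by water deficit and in anthocyanin and polyamine biosynthesis. Chloroplast genes held a median of 21.9% of counts in emerging leaves and 68.6% (62.2 to 78.6%) in expanding leaves, where psbA alone held 37.3 to 65.3%. The depth left for nuclear genes was therefore lower in expanding leaves, at 4.74 to 10.0 M counts per library. In emerging leaves chloroplast shares were 20.8 ± 1.04% in well-watered and 24.03 ± 0.143% in water-deficit Col-0, and 20.1 ± 2.36% and 22.4 ± 1.39% in gtl1-4 (n = 3 each). Chloroplast shares in expanding leaves were 69.7 ± 1.23% in well-watered Col-0, 71.9 ± 6.04% in water-deficit Col-0, 67.5 ± 5.12% in well-watered gtl1-4 and 65.8 ± 3.41% in water-deficit gtl1-4.

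GTL1 (AT1G33240) was lower in every gtl1-4 library than in any Col-0 library of the same leaf age and water supply. In emerging leaves its normalized count was 1450 ± 66.5 in well-watered Col-0 and 335 ± 43.8 in well-watered gtl1-4 (log2 fold change -2.12, SE 0.15, adjusted p 1.21e-06), so 23.1% of the Col-0 level remained on the fitted scale. In expanding leaves it was 823 ± 113 in Col-0 and 272 ± 44.6 in gtl1-4 (-1.60, SE 0.16, adjusted p 8.00e-05), or 33.0%. Under water deficit 17.7 and 27.2% remained. An exact two-sided permutation test of 6 against 6 libraries that pooled both water supplies gave p 0.00216 in each leaf age, the smallest it can give, and 3 against 3 cannot go below 0.1. The gene lies on chromosome 1 of TAIR10.1 at 12051361 to 12054753 on the minus strand, with 3 annotated transcripts of 2 to 3 exons. The position of the insertion is not given in the sources used here, so reads outside it can remain.

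GTL1 also fell with water deficit. In Col-0 it dropped to 1038 ± 117 in emerging leaves (-0.49, SE 0.15, adjusted p 0.0378) and to 503 ± 75.9 in expanding leaves (-0.71, SE 0.16, adjusted p 0.00903). The remaining GTL1 reads of gtl1-4 fell as well, by 0.87 in emerging and by 0.99 in expanding leaves on the log2 scale (adjusted p 0.00169 and 0.00168), and the difference between the genotypes did not pass (adjusted p 0.889 and 0.882). The call in emerging leaves of Col-0 was lost in 5 of 6 fits without 1 replicate, all but that without water-deficit replicate 1, with adjusted p up to 0.127, and over all alternatives its adjusted p was 0.00759 to 0.127. In expanding leaves it was kept in all 6, with adjusted p up to 0.0498 without water-deficit replicate 1.

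**Figure D1:**
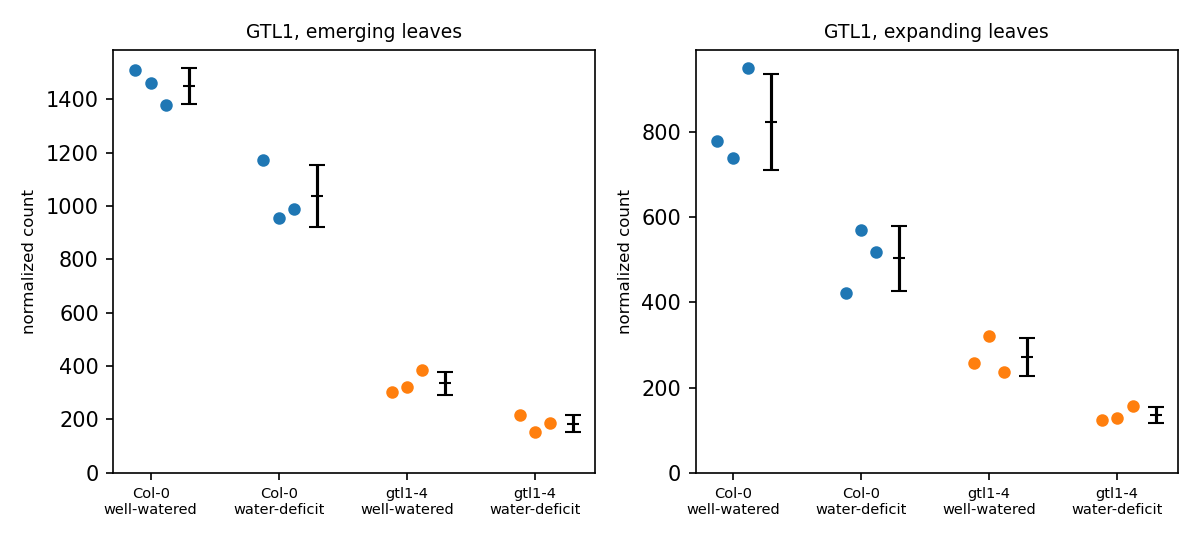
Normalized count of GTL1 in each library (points, 3 per group) with the group mean and standard deviation (black), for emerging leaves on the left and expanding leaves on the right, which were scaled separately. Col-0 is blue and gtl1-4 orange, and the gtl1-4 means of 335 and 184 in emerging leaves and 272 and 136 in expanding leaves lie below all Col-0 values.

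In emerging leaves of Col-0, water deficit raised genes of dehydration protection and anthocyanin synthesis and lowered genes of DNA replication and water transport. Of the lists for these groups, only that of anthocyanin enzymes also passed with an estimated correlation. HIS1-3, a linker histone variant induced by drought, went from 12.6 ± 15.1 to 1128 ± 402 normalized counts (log2 fold change 6.90, SE 0.56, adjusted p 3.10e-06, n = 3). LEA7 was listed at 0 in the well-watered libraries and at 115 ± 62.6 under deficit, and the phosphatase gene HAI2 rose by 6.04. Falls included AT3G16670 (-4.81), AT4G19430 (-4.78), CYP71B22 (-4.67) and MSRB9 (-4.50). Altogether 1200 genes rose and 1239 fell, of which 309 and 221 changed at least 2-fold.

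Of 16 anthocyanin enzyme genes, 15 rose over all genes tested and also 15 adjusted over the list alone, with a median of 1.48. F3PRIMEH, the flavonoid 3'-hydroxylase gene TT7, rose by 2.09, LDOX by 1.70, UGT75C1 by 1.62, and DFR, for dihydroflavonol reductase, went from 3229 ± 445 to 9111 ± 1284 (adjusted p 5.17e-06). The list passed at the preset correlation (adjusted p 9.96e-21) and with an estimated correlation (adjusted p 0.00621). The activators TT8 and MYB75 rose by 1.95 and 0.87, while MYB90 was at -0.02 with adjusted p 0.990. The repressor gene HAT1 fell by 1.56, a call lost in 5 of 6 fits without 1 replicate, all but that without water-deficit replicate 1 (adjusted p up to 0.145).

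Of 38 dehydration and abscisic acid response genes 25 rose and 1 fell, or 28 and 1 adjusted over the list alone, with a median of 1.45. RD29B was listed at 0 in the well-watered libraries and at 32.7 ± 10.5 under deficit, a call lost without water-deficit replicate 1 (adjusted p 0.0767). The list passed (adjusted p 7.18e-15), but not with an estimated correlation (adjusted p 0.163). In DNA replication 6 of 8 genes fell, or 7 adjusted over the list alone, among them PCNA1 (-0.93) and TSO2 (-0.61), with adjusted p 0.000250, and adjusted p 0.356 with an estimated correlation. Of 17 aquaporins 7 fell, including TIP2;1 (-1.19) and TIP1;1 (-0.73), and 1 rose, or 9 and 1 adjusted over the list alone (adjusted p 0.00983, and adjusted p 0.489 with an estimated correlation).

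Polyamine synthesis genes moved in both directions, 3 up and 3 down of 18, both over all genes and adjusted over the list alone. ADC2, which encodes arginine decarboxylase, the entry to putrescine synthesis, rose by 1.41 (1905 ± 225 to 5098 ± 1001, adjusted p 0.000630), as did SAMDC3 by 1.41. AIH and MAT4 fell by 1.18 and 0.70. ADC1 (-0.25), SPDS1 (-0.02), SPDS2 (0.16) and SAMDC1 (0.03) did not pass, and the list as a whole did not shift (adjusted p 0.991). CCS52A1, an endocycle activator, fell by 0.64, and SDD1, a stomatal density gene, was at -0.50 with adjusted p 0.123.

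The count of 2439 genes fell to 1280, 1439 and 1227 without well-watered replicate 1, 2 or 3 and to 1249 without water-deficit replicate 1. Of 67 named and called genes, 43 kept their call in every fit without 1 replicate. SAMDC3 lost it in 5 of 6 such fits (adjusted p up to 0.160), AIH in 3 (up to 0.0891) and CCS52A1 in 3 (up to 0.110).

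In emerging leaves of gtl1-4, water deficit again raised dehydration and anthocyanin genes. HIS1-3 rose by 6.26 and AT3G56275 by 5.86, LEA7 was listed at 0 when well-watered and at 223 ± 270 under deficit, and AT4G19430 and MEE3 fell by 5.04 and 4.89. In all 922 genes rose and 722 fell. Of 16 anthocyanin enzyme genes 15 rose, or 16 adjusted over the list alone (median 1.24, adjusted p 4.28e-21, and adjusted p 0.00585 with an estimated correlation), with DFR at 1.39 and LDOX at 1.25. Of 38 dehydration genes 21 rose and 1 fell, or 27 and 2 adjusted over the list alone (adjusted p 6.62e-16, and adjusted p 0.139 with an estimated correlation). ADC2 rose by 0.98, SPMS by 0.41 and SPDS2 by 0.40, and MAT4 fell by 0.61. SPMS lost its call without water-deficit replicate 1 or well-watered replicate 2 (adjusted p up to 0.0682) and SPDS2 in 4 of 6 such fits (up to 0.143). The count of 1644 was 791, 888, 991 and 1004 without well-watered replicate 1, well-watered replicate 2, water-deficit replicate 1 and water-deficit replicate 2. It was 789 in a fit of only the 2 groups, 1043 without a variance trend and 2772 with array weights.

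In expanding leaves of Col-0, water deficit raised anthocyanin and dehydration genes and lowered genes of cell wall loosening, water transport and glucosinolate synthesis. Of the lists for these groups, only that of dehydration genes also passed with an estimated correlation. LEA4-5, a late embryogenesis abundant protein gene, went from 0.653 ± 0.604 to 136 ± 62.5 (6.35, SE 0.68, adjusted p 2.30e-05), and DAA1 and RD29B rose by 5.77 and 5.55. XTH24, a xyloglucan endotransglucosylase gene of the cell wall, fell from 341.5 ± 52.8 to 9.88 ± 8.71 (-5.76, SE 0.73, adjusted p 0.000103). ACS4 and BAM5 fell by 4.07 and 3.63. In all 1021 genes rose and 1210 fell, 491 and 446 of them at least 2-fold.

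Of 16 anthocyanin enzyme genes 12 rose, or 13 adjusted over the list alone, with a median of 2.49. DFR went from 56.0 ± 33.1 to 1399 ± 573 (4.69, SE 0.33, adjusted p 4.28e-07), 3AT1 rose by 4.35, GSTF12 by 3.71 and LDOX by 3.70. The list passed (adjusted p 4.32e-11), though not with an estimated correlation (adjusted p 0.227). TT8 and MYB75 rose by 3.65 and 1.68, and 4 of 6 anthocyanin repressor genes fell, or 5 adjusted over the list alone, led by LBD38 (-2.34) and HAT1 (-1.52; adjusted p 0.000239, and adjusted p 0.227 with an estimated correlation). Dehydration genes rose in 23 of 36 cases, or 27 adjusted over the list alone (median 1.16, adjusted p 6.19e-17), and passed with an estimated correlation (adjusted p 0.0436).

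Of 16 aquaporins 12 fell, or 13 adjusted over the list alone and 1 higher, with PIP1;5 at -1.80 and TIP2;1 at -1.73, and PIP2;5 rose by 1.49. Of 10 cell wall expansion genes 6 fell, or 7 adjusted over the list alone, led by XTH4 (-2.59) and XTH9 (-2.22). Adjusted p was 7.78e-07 and 6.68e-05 for these lists, and adjusted p 0.377 and 0.227 with an estimated correlation. Of 16 aliphatic glucosinolate genes 7 fell, or 12 lower and 1 higher adjusted over the list alone, such as SUR1 (-0.82; list adjusted p 0.000328, and adjusted p 0.545 with an estimated correlation). Of 6 indole glucosinolate genes 3 fell, or 5 adjusted over the list alone, with CYP83B1 at -1.21 (adjusted p 0.00587, and adjusted p 0.346 with an estimated correlation).

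Among 18 polyamine synthesis genes 4 rose and 4 fell, or 6 and 5 adjusted over the list alone. SAMDC3 and ADC2 rose by 1.62 and 1.45, ADC2 from 185 ± 35.8 to 511 ± 123, and SPDS2 by 0.37. MAT4 fell by 1.19 and ADC1 by 0.65, while SPDS1 (0.26) and SAMDC1 (-0.03) did not pass. The list as a whole did not shift (adjusted p 0.420). CCS52A1 fell by 0.81, and the genes SDD1 and MYB90 were below the filter.

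The count of 2231 fell to 1462 without water-deficit replicate 1, to 1131 in a fit of only the 2 groups and to 1416 without well-watered replicate 3 and water-deficit replicate 2 together. Of 70 named and called genes 50 kept their call in every fit without 1 replicate, and SPDS2 lost it in all 6 (adjusted p up to 0.170), CCS52A1 in 5 (up to 0.145), and ADC1 without water-deficit replicate 3 (0.0507).

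In expanding leaves of gtl1-4, 390 genes rose and 397 fell with water deficit. RD29B rose from 0.470 ± 0.815 to 343 ± 267 (7.73, SE 0.51, adjusted p 2.84e-07), and AT5G15500 and AT2G35070 rose by 5.91 and 5.34. XTH24 and UMAMIT17 fell, at -3.87 and -3.74. Of 16 anthocyanin enzyme genes 8 rose, or 13 adjusted over the list alone (median 1.63, adjusted p 9.45e-12, and adjusted p 0.150 with an estimated correlation), with DFR at 2.38 and LDOX at 2.23. Dehydration genes rose in 23 of 36 cases, or 28 and 1 lower adjusted over the list alone (adjusted p 5.60e-26, and adjusted p 0.0111 with an estimated correlation). Of 16 aquaporins 10 fell, or 12 and 1 higher adjusted over the list alone (adjusted p 3.58e-08, and adjusted p 0.246 with an estimated correlation). ADC2 rose by 0.79, a call lost in 4 of 6 fits without 1 replicate (adjusted p up to 0.158), and ADC1 fell by 0.97. The count of 787 was 466, 389 and 519 without water-deficit replicate 1, water-deficit replicate 2 and well-watered replicate 2. It was 1265 in a fit of only the 2 groups, 1772 with array weights and 1344 without the Col-0 libraries well-watered replicate 3 and water-deficit replicate 2.

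The water responses of the genotypes shared many genes. In emerging leaves 1048 genes were called in both in the same direction (603 higher, 445 lower, 0 opposite), where independent lists would share 59.7 and 48.3. In expanding leaves 625 were shared (295 higher, 330 lower, 0 opposite), against 24.1 and 29.1. The correlation across genes of the log2 fold changes was 0.630 and 0.666, and genes are not independent replicates. These responses have no library in common.

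In emerging leaves the genotypes differed in few genes. When well-watered, 18 genes were higher and 12 lower in gtl1-4, and under water deficit 24 were higher and 10 lower. AT1G75945 was 279 ± 57.1 in well-watered gtl1-4 against 0.444 ± 0.769 in Col-0 (7.70, SE 0.52, adjusted p 1.21e-06), and AT2G23900 and AT5G35935 were higher by 6.64 and 4.79. AT3G01345 was 111 ± 182 in well-watered gtl1-4 against 4294 ± 123 in Col-0 (-7.49, SE 1.09, adjusted p 0.00489), and MRD1 was lower by 3.22. In both treatments together 22 genes were called in the same direction, where independent lists would share 0.0233 higher and 0.00648 lower.

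Of the anthocyanin enzyme genes 0 of 16 were called with limma when well-watered, over all genes or adjusted over the list alone (8 higher and 1 lower at an unadjusted p under 0.05), although the list was higher in gtl1-4 (median 0.27, adjusted p 0.000340, and adjusted p 0.677 with an estimated correlation). Photosynthesis genes were lower as a list (median -0.13, adjusted p 3.69e-05, and adjusted p 0.747 with an estimated correlation), with 0 of 28 called, 2 lower adjusted over the list alone and 5 lower at an unadjusted p under 0.05. LDOX (0.43), DFR (0.18), ADC2 (0.38), ADC1 (0.09), SDD1 (-0.17) and CCS52A1 (0.13) did not pass, nor did any of them under water deficit. Under water deficit the touch gene XTH22 was lower (-1.19, adjusted p 0.00410), as were the touch list (adjusted p 0.0223, and adjusted p 0.310 with an estimated correlation) and the heat shock list (adjusted p 0.0223, and adjusted p 0.676 with an estimated correlation). The well-watered count of 30 was 17, 19 and 19 without Col-0 replicate 1, 2 or 3, and 773 with array weights.

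In well-watered expanding leaves gtl1-4 differed in more genes, 117 higher and 105 lower, 70 and 50 of them at least 2-fold. DFR was 340 ± 23.2 in gtl1-4 against 56.0 ± 33.1 in Col-0 (2.74, SE 0.33, adjusted p 0.000569), and the anthocyanin genes GSTF12, LDOX and 5MAT were higher by 2.34, 2.01 and 1.71. ADC2 was 342 ± 49.1 against 185 ± 35.8 (0.89, SE 0.19, adjusted p 0.0327), and ADC1 was 442 ± 45.7 against 277 ± 30.3 (0.67, SE 0.16, adjusted p 0.0499). The dehydration genes RD29B, GOLS2, HB7 and KIN2 were lower (-2.95, -1.24, -1.01 and -0.90), with RD29B near the floor in well-watered gtl1-4. Higher were also AT5G35935 (5.90), AT1G75945 (5.32) and CAD2 (4.27), and lower were AT3G01345 (-7.26), AT4G04410 (-3.57) and VSR7 (-3.26).

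Of 16 anthocyanin enzyme genes 6 were higher, or 10 adjusted over the list alone (median 1.22, adjusted p 1.72e-07, and adjusted p 0.449 with an estimated correlation). Of 18 polyamine synthesis genes 2 were higher, or 5 higher and 1 lower adjusted over the list alone (adjusted p 0.0364, adjusted p 0.0610 with the replicate block, and adjusted p 0.449 with an estimated correlation). Photosynthesis genes were higher as a list (median 0.22, 26 of 28 positive, adjusted p 0.00296), a call lost with quantile scaling (adjusted p 0.621) and with an estimated correlation (adjusted p 0.487), with limma calling 0 of 28 over all genes or adjusted over the list alone and 3 higher at an unadjusted p under 0.05. The difference from emerging leaves was not tested. Jasmonate genes were higher as a list (median 0.57, 16 of 19 positive, adjusted p 0.00335, and adjusted p 0.487 with an estimated correlation), with 1 called and 5 adjusted over the list alone. So were flavonol and phenylpropanoid genes (median 0.33, 7 of 7 positive, adjusted p 0.0319, and adjusted p 0.487 with an estimated correlation), with limma calling 0 of 7 over all genes or adjusted over the list alone and 3 higher at an unadjusted p under 0.05. Of 36 dehydration genes 6 were lower, or 8 adjusted over the list alone (median -0.09, 15 of 36 positive, adjusted p 0.0211, and adjusted p 0.487 with an estimated correlation). TT8 was at 1.93 with adjusted p 0.147, and MYB75 (0.20), SPDS1 (0.13), SPDS2 (-0.03), SAMDC1 (0.44) and CCS52A1 (-0.27) did not pass either. Higher in gtl1-4 were also the cyclin genes CYCD3;2 (1.17) and CYCD3;1 (1.12), the jasmonate methyltransferase gene JMT (1.78), EXPA1 (0.64) and DF1 (1.14), a trihelix gene related to GTL1.

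The count of 222 was 126 and 114 without Col-0 replicate 1 or 3, and 104, 117 and 79 without gtl1-4 replicate 1, 2 or 3. It was 81 in a fit of only the 2 groups and 123 without a variance trend. Of 25 named and called genes 15 kept their call in every fit without 1 replicate. DFR was kept in all, LDOX and 5MAT were lost without gtl1-4 replicate 3, with adjusted p 0.0715 and 0.0654, and GSTF12 without gtl1-4 replicate 2 or 3 (up to 0.0654). ADC2 and KIN2 were lost in 4 of 6 fits (up to 0.128 and 0.135), CYCD3;2, CYCD3;1 and JMT in 5 (up to 0.0822, 0.142 and 0.133), and ADC1 and EXPA1 in 6 (up to 0.190 and 0.137).

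Under water deficit, 21 genes were higher and 7 lower in expanding leaves of gtl1-4, among them AT1G75945 (5.58), AGL38 (5.15) and CAD2 (4.17) on the higher and AT3G01345 (-8.87) and MRD1 (-3.96) on the lower side. DFR (0.43), LDOX (0.54), ADC2 (0.23) and ADC1 (0.35) did not pass, and 0 of 16 anthocyanin enzyme genes were called, over all genes or adjusted over the list alone, with 1 higher at an unadjusted p under 0.05. That list was higher (median 0.32, adjusted p 0.00694, and adjusted p 0.807 with an estimated correlation). Aquaporins were higher as a list (median 0.35, adjusted p 2.29e-05, and adjusted p 0.692 with an estimated correlation), with 4 of 16 called adjusted over the list alone. Lists of cell wall expansion (adjusted p 0.000372, and adjusted p 0.448 with an estimated correlation), aliphatic glucosinolate (adjusted p 0.00117 and 0.807), jasmonate (0.00288 and 0.807), stomatal lineage (0.00310 and 0.195) and mitotic genes (0.00719 and 0.448) were higher too, and that of dehydration genes was lower (0.000641 and 0.448). Limma called 0 of their genes over all genes, with 5, 1, 4, 3 and 2 higher and 3 lower at an unadjusted p under 0.05, and adjusted over the list alone 5 cell wall and 4 jasmonate genes. Of the genes called in either treatment, 20 were called in both in the same direction. The count of 28 was 54 without Col-0 replicate 3, and 15, 17 and 17 without gtl1-4 replicate 1, 2 or 3, and 112 with array weights.

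**Figure D2:**
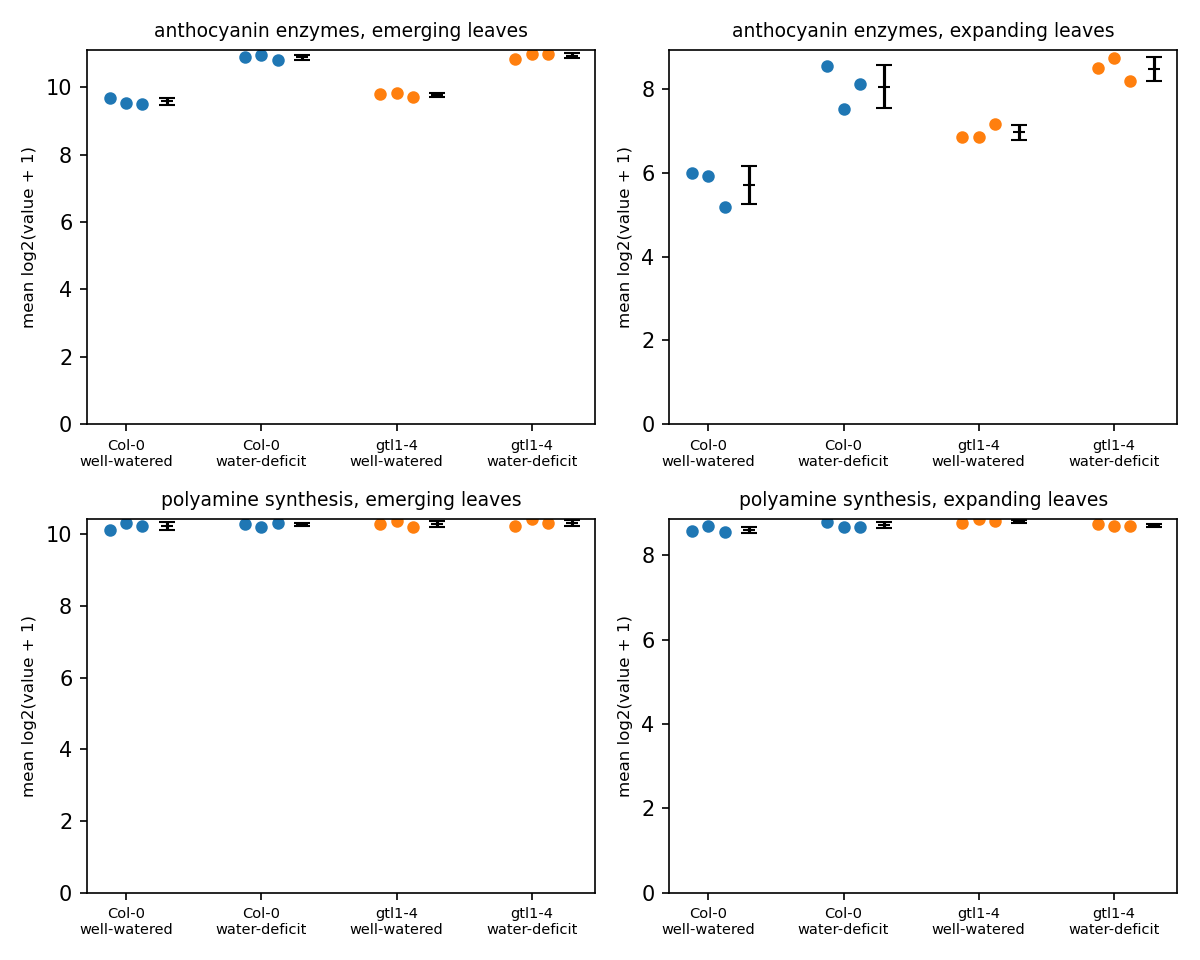
Mean log2(value + 1) over the tested genes of the anthocyanin enzyme list (top) and the polyamine synthesis list (bottom) in each library, with the group mean and standard deviation (black), for emerging leaves on the left and expanding leaves on the right. Col-0 is blue and gtl1-4 orange, and the anthocyanin means rise with water deficit in both genotypes.

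The test of whether the water response differed between genotypes called 0 genes in emerging leaves (987 at an unadjusted p under 0.05, smallest adjusted p 0.889) and 0 genes in expanding leaves (948, smallest adjusted p 0.181) with limma, and limma-voom also called 0. Adjusted over all genes, the higher count of genotype calls in well-watered than in water-deficit expanding leaves is therefore not shown to be a difference for any gene. Adjusted over the list alone, 5 of 16 anthocyanin enzyme genes and 1 of 18 polyamine synthesis genes had a lower water response in expanding leaves of gtl1-4. DFR had the difference -2.31 (adjusted p 0.679) and ADC2 -0.66 (adjusted p 0.845). The expanding count was 2 without well-watered Col-0 replicate 1 or 2 and 1 without well-watered gtl1-4 replicate 2, and the emerging count was 1 without water-deficit Col-0 replicate 1.

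The genotype effect in well-watered expanding leaves correlated with the water response of Col-0 across genes at 0.420, but both use the same 3 well-watered Col-0 libraries, and unchanged groups simulated against them gave 0.501. The covariance was 0.129 against a simulated 0.0484. Of 222 and 2231 calls 56 were shared higher, 27 lower and 21 opposite, where unchanged groups simulated against the same libraries shared a mean of 0 higher and 0.01 lower. Independent lists would share 7.23 and 7.69, a value that leaves out the shared controls, as the simulated one leaves out the effects, so neither excess shows a shared effect. In emerging leaves the covariance was 0.0571 against 0.0555. There the well-watered Col-0 libraries ranked 9, 11 and 10, so the simulated value can be too high. The excess can therefore not be compared between leaf ages. With the 3 controls divided into 1 and 2 so that the effects shared no library, the 6 divisions, chosen after the result was seen, gave covariances of 0.0211 to 0.0571 (mean 0.0385) in expanding and 0.00352 to 0.0341 (mean 0.0163) in emerging leaves. These divisions reuse the same libraries and are not independent. Part of the excess over the simulated covariance, without division, may come from the shared controls.

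Markers of other tissues and of handling were also measured. Touch genes were lower as a list under water deficit in emerging leaves of Col-0 (2 of 3 fell, also adjusted over the list alone, XTH22 by 1.60; adjusted p 0.0120, and adjusted p 0.163 with an estimated correlation) and of gtl1-4 (2 of 3, or 3 adjusted over the list alone, XTH22 by 2.61; adjusted p 0.000659, and adjusted p 0.0569 with an estimated correlation). In expanding leaves the list passed in gtl1-4 (2 of 4 fell, or 3 adjusted over the list alone; adjusted p 0.00345, and adjusted p 0.232 with an estimated correlation) and in Col-0 only with the replicate block (adjusted p 0.0229) or quantile scaling (0.0387), against 0.0662. CML12 fell there by 2.13 in Col-0 and by 1.78 in gtl1-4, the latter lost in 3 of 6 fits without 1 replicate (adjusted p up to 0.152). The heat shock gene HSP90.1 rose in emerging leaves by 1.19 in Col-0 and by 0.84 in gtl1-4, the latter lost in 3 of 6 such fits (up to 0.131). The clock gene LHY fell in Col-0 by 0.87 in emerging leaves, a call lost without well-watered replicate 2 (adjusted p 0.0535), and by 1.07 in expanding leaves, and in gtl1-4 by 1.19 and 1.21. Other morning clock genes rose, in emerging leaves PRR7 (0.75) and PRR9 (0.70) in Col-0 and PRR9 (0.66) in gtl1-4. In expanding Col-0 CCA1 rose by 0.44 and CDF1 fell by 0.46. In emerging leaves the morning clock list did not pass with camera (adjusted p 0.176 in Col-0 and 0.362 in gtl1-4). Camera cannot show opposite shifts in a list. The evening clock gene GI rose in these leaves by 0.57 in Col-0 and 0.63 in gtl1-4, and PRR5 rose in gtl1-4. The evening list did not pass there (adjusted p 0.144 and 0.0774). In expanding leaves 0 of 3 were called, but 3 rose in Col-0 and 2 in gtl1-4 adjusted over the list alone. That list passed in gtl1-4 (adjusted p 0.0315, and 0.246 with an estimated correlation). It passed in Col-0 only with quantile scaling (0.0387), against 0.0662. Limma called 0 mitotic genes in each comparison, with up to 4 of 16 at an unadjusted p under 0.05 in emerging gtl1-4. In guard cell genes GC1 fell by 3.16 in emerging and by 1.88 in expanding leaves of Col-0. In gtl1-4 it fell by 1.71 in emerging leaves, a call lost without well-watered replicate 3 (adjusted p 0.0627), and was at -0.71 in expanding leaves with adjusted p 0.470. KAT1 fell in expanding leaves, by 0.90 in Col-0 and by 1.25 in gtl1-4. In emerging leaves GC1 was the 1 of 9 guard cell genes called, and the list did not pass with camera (adjusted p 0.135 in Col-0 and 0.163 in gtl1-4). In expanding Col-0 3 of 9 were higher and 2 lower at an unadjusted p under 0.05.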

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

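The tests of the difference between genotypes were planned, and the comparison of leaf ages was not a test. In expanding leaves the water response of gtl1-4 was below that of Col-0 for anthocyanin enzymes, with a median log2 difference of -0.73 (adjusted p 0.00294, and adjusted p 0.888 with an estimated correlation), and for polyamine synthesis genes, with a median difference of -0.22 (adjusted p 0.0328, adjusted p 0.0518 with the replicate block, and adjusted p 0.888 with an estimated correlation). It was above that of Col-0 for aliphatic glucosinolate genes, with a median difference of 0.34 (adjusted p 0.0113, and adjusted p 0.888 with an estimated correlation). In emerging leaves it was above that of Col-0 for photosynthesis genes, with a median difference of 0.16 (adjusted p 0.0459, adjusted p 0.0707 with the replicate block, 0.381 with quantile scaling, and adjusted p 0.909 with an estimated correlation). None of the 4 held with an estimated correlation. Limma called 0 of their genes over all genes. Adjusted over the list alone, 5 of 16 anthocyanin enzyme genes and 1 of 18 polyamine synthesis genes were lower, and 0 genes of the other lists passed.

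Indole glucosinolate genes separated all water-deficit from all well-watered libraries of gtl1-4 in opposite directions at the 2 leaf ages, with a median change of 0.35 in emerging and -0.85 in expanding leaves. In gtl1-4 limma called 0 of 5 genes in emerging leaves, over all genes or adjusted over the list alone, with 1 higher at an unadjusted p under 0.05 (list adjusted p 0.205), and 3 of 6 fell in expanding leaves, or 5 adjusted over the list alone (adjusted p 0.000217, and adjusted p 0.150 with an estimated correlation). Col-0 had medians in the same directions, 0.46 in emerging leaves (0 of 5 called, 3 higher at an unadjusted p under 0.05, list adjusted p 0.0827) and -0.74 in expanding leaves (3 of 6 fell, or 5 adjusted over the list alone, list adjusted p 0.00587, and adjusted p 0.346 with an estimated correlation), but its emerging libraries overlapped. The tables were scaled separately, and the difference between leaf ages was not tested.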

How the results depend on the processing

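Limma-voom weights, the correlations without 1 replicate and the fits without 2 libraries were chosen after the data were seen. No called result reversed, while directions of some lists and genes that were not called did turn. Over the alternatives, counts of genes stayed within 1.5 times in 156 cases and moved further in 44. The cause of these changes was not tested, and fits with fewer libraries or groups gave lower counts in some comparisons and higher ones in others. With only the 2 groups compared, the counts were 1131 for water deficit in expanding Col-0, 789 and 1265 for gtl1-4 in emerging and expanding leaves, and 81 for genotype in well-watered expanding leaves. Array weights gave 2772 and 1772 for water deficit in gtl1-4, 773 for genotype in well-watered emerging and 112 in water-deficit expanding leaves. Without a variance trend the counts were 1043 for water deficit in emerging gtl1-4 and 123 for genotype in well-watered expanding leaves. Without the 2 libraries farthest from their groups, water deficit in emerging gtl1-4 gave 1008 genes, and 889 without the 2 picked by eye. In expanding leaves both choices fell on the same libraries and gave 1416 genes in Col-0 and 1344 in gtl1-4.

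Without 1 replicate, water deficit gave 1227 to 2249 genes in emerging and 1462 to 2140 in expanding Col-0, and 791 to 1859 and 389 to 559 in gtl1-4. Genotype gave 17 to 38 and 79 to 214 genes when well-watered in emerging and expanding leaves, and 27 to 35 and 15 to 54 under water deficit. The interaction gave 0 to 1 and 0 to 2. The fall of GTL1 in emerging Col-0 was -0.43 to -0.58 without 1 replicate. It missed the threshold at -0.49 without a low-value filter (adjusted p 0.0503) and without a variance trend (adjusted p 0.0669), and at -0.43 with either choice of 2 libraries left out (adjusted p 0.116 by eye and 0.0812 by distance). Its adjusted p over all alternatives was 0.00759 to 0.127.

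With an estimated correlation, 1 list stayed past the threshold for water deficit in each genotype and leaf age, and 0 for genotype and interaction. The photosynthesis call of the emerging interaction went to 0 lists also with quantile scaling and with the replicate block. The correlation of water responses was 0.696 and 0.737 in emerging and expanding leaves with a mean of at least 50, and 0.562 to 0.648 and 0.605 to 0.672 without 1 replicate. In expanding leaves the genotype effects of both treatments correlated at 0.378 with a mean of at least 50 and at 0.254 to 0.335 without 1 replicate, and at 0.0706 to 0.272 in emerging leaves. The genotype effect and the Col-0 water response correlated at 0.329 with a mean of at least 50 and 0.321 with quantile scaling in expanding leaves, and at 0.364 to 0.547 and, in emerging leaves, 0.158 to 0.369 without 1 replicate.

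Libraries of equal replicate number seldom deviated together within a leaf age. The correlation of deviations was over 0.1 in 3 of 18 pairs in emerging and 2 of 18 in expanding leaves. It ran from -0.283 to 0.200 and from -0.161 to 0.133. No reference value was set and leaf ages were not compared, so pairing by replicate number is not ruled out. With the replicate block no count of genes moved by over 1.5 times. Water deficit in emerging Col-0 called 2135 genes and in expanding Col-0 1999. With the block the polyamine list lost its call for genotype in well-watered expanding leaves and for the interaction there. Simulated 2-fold changes were recovered in 76.1% of cases in emerging and 53.7% in expanding leaves for the Col-0 water response, and in 52.2 and 55.2% for genotype. At 4-fold these were 86.4 and 92.4%, and 86.4 and 95.5%. Whether depth sets them was not tested.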

Other observations

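The tests on chromosome position, on neighbouring genes, on replicate 3 and on mixed pools, the divided controls and the splits of the libraries were chosen after the result was seen. Single genes of other lists also changed with water deficit. The small Rubisco subunit gene RBCS1B fell in Col-0 by 0.93 in emerging and by 1.17 in expanding leaves, and in gtl1-4 by 0.66 and 1.06. The defence gene PR5 fell in Col-0 by 1.60 and 2.51, and VSP2, a jasmonate-responsive gene, rose by 1.60 in emerging leaves. NAP, a senescence regulator gene, rose by 1.95 in emerging Col-0. The lists in emerging Col-0 did not pass for jasmonate (2 of 18 up, or 2 up and 2 down adjusted over the list alone; adjusted p 0.980), senescence (1 of 5 up, also adjusted over the list alone; adjusted p 0.632) and salicylic acid and defence (2 of 11 down, or 1 up and 2 down adjusted over the list alone; adjusted p 0.357). The photosynthesis list was higher there, against the direction of RBCS1B, with 3 of 28 up and 1 down, also adjusted over the list alone (adjusted p 0.0226, adjusted p 0.103 with quantile scaling, and adjusted p 0.616 with an estimated correlation). In expanding Col-0 the jasmonate list was lower with 2 of 19 down, also adjusted over the list alone (adjusted p 0.0213, and adjusted p 0.547 with an estimated correlation), as was the defence list with 1 of 11, or 2 adjusted over the list alone (adjusted p 0.0329, and adjusted p 0.227 with an estimated correlation). Photosynthesis genes as a list were higher in emerging gtl1-4 under deficit, with 4 of 28 up and 1 down, or 5 and 1 adjusted over the list alone (adjusted p 2.24e-06, and adjusted p 0.360 with an estimated correlation). In expanding leaves of gtl1-4 jasmonate genes were lower under deficit, with 3 of 19 called, or 6 adjusted over the list alone, and 1 higher in the latter (adjusted p 0.000217, and adjusted p 0.430 with an estimated correlation).

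A total of 36 genes other than GTL1 were called in at least 2 of the 4 comparisons of the lines. ESM1, chosen after its values were seen, was higher in gtl1-4 in all 4, by 1.55 and 1.62 in emerging and by 2.82 and 2.79 in expanding leaves. DNA linked to the insertion would place many of them near GTL1, but 0% lay within 1000 gene positions of it, against 3.51% of all tested genes, which argues against that origin for the group. Differing DNA elsewhere in the genome could give neighbouring pairs, and 1 pair lay within 5 positions, AT2G23890 and AT2G23900, against a mean of 0.190 in 10000 random sets (p 0.173) and 0.197 in sets of water-response genes (p 0.178), which leaves that hypothesis open. A direct or indirect effect of GTL1 loss was not tested.

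The genotype effect in well-watered expanding leaves ran along the water response of Col-0 with a covariance above the simulated one, which can be too low. If that came only from the shared Col-0 libraries, it should vanish against the water response of emerging leaves, which shares none, and the correlation across 16185 genes was -0.0239 there. An effect limited to expanding leaves could give the same value. Shared libraries as the only source should also leave no covariance with divided controls, which share no library. The covariance was 0.0211 to 0.0571 there, which goes against that source, but the divisions are not independent. The correlation with emerging leaves cannot tell shared libraries from an effect limited to expanding leaves, and reused libraries limit the divided controls. The shared libraries as the only source therefore stay open. Without well-watered Col-0 replicate 3 the covariance less its expected value was 0.0438. With all libraries it was 0.0805, without replicate 1 0.132 and without replicate 2 0.151. The expected value was computed from the spread shared by the 4 groups. It can be too low in fits that keep replicate 3, which lay farthest from its group mean. The value without replicate 3 lies above the bound set for excluding that library by less than the spread of 0.0279 between such fits. That library as the source therefore stays open.

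GTL1 reads remained in gtl1-4, at a median of 20.8% of the Col-0 mean in emerging and 30.0% in expanding leaves. Col-0 plants in the pools could leave such reads but would bring every other Col-0 transcript at that share too, and in 12 of 12 gtl1-4 libraries at least 2 abundant genes lay below the GTL1 share, even with each gene set against its lowest and GTL1 against its highest Col-0 library, which argues against such plants as the whole source. In the median library 2 genes, AT3G01345 and MRD1, were below 0.5 times the GTL1 share, fewer than the 3 genes set as another bound. Their medians were 0.114 and 6.04% in emerging and 0 and 9.10% in expanding leaves. A smaller Col-0 share therefore stays open. By the same reasoning it would be at most that of AT3G01345, the lowest of these genes in each gtl1-4 library. AT3G01345 was at 0 to 0.220% of its lowest Col-0 library, and at 7.72 and 9.77% in well-watered replicate 2 of emerging and expanding leaves. Reads of the related gene DF1 could also be counted as GTL1, and DF1 had water responses in gtl1-4 of -0.32 in emerging and -0.40 in expanding leaves, neither called, which lie between the bounds. A truncated transcript that still responds to water was not tested.

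AT3G01345 was at 321 in emerging and 50.8 in expanding leaves of well-watered gtl1-4 replicate 2, which is 7.48 and 8.88% of the Col-0 mean, and at 0 to 9.15 in every other gtl1-4 library.

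With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each of the 8 comparisons. Water deficit gave 2439 genes in emerging Col-0 with 1 in the highest other split, 1644 in gtl1-4 with 1, 2231 in expanding Col-0 with 1 and 787 in gtl1-4 with 0. Genotype gave 30 and 34 genes in emerging leaves with 0 and 1, and 222 and 28 in expanding leaves with 37 and 0. For the interaction 0 genes were found, so 100 of 100 regroupings give at least as many by design, which says nothing about chance. The highest regrouping gave 4156 genes in emerging and 2384 in expanding leaves, the next 278 and 2, and it parted 12 of 12 libraries as the water supply does, so it points to that structure of the samples.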
